A study of Arabidopsis thaliana with 8 samples.

How the data were processed

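Chromatin-affinity precipitation followed by sequencing (ChAP-seq) recovers the DNA that is found together with a tagged molecule in crosslinked nuclei. Here the tagged molecule was a biotin-labelled tRNA-derived fragment (tRF), a short RNA with the sequence of part of a tRNA. It was infiltrated by syringe into leaves of Arabidopsis thaliana ecotype Col-0 at 3.5 weeks of age, either in its wild-type sequence or in a mutant sequence that served as the control, and the leaves were treated for 1 h. Per the labels' protocols, the tissue was crosslinked with 1% formaldehyde for 15 min, the nuclei were lysed and sonicated for 10 cycles, and biotin-bound DNA was captured on streptavidin beads. The labels name neither the tRNA nor the changed bases.

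There were 8 samples, 4 per tRF, numbered as replicates 1 to 4 in the labels. Every sample had a file of sequenced DNA fragments, and every wild-type tRF sample also had a peak list. The TAIR10 build, cutadapt 2.10, Trimmomatic 0.36, Bowtie2 2.2.9 and MACS2 are named in the submitters' processing notes, with no role or order. The deposited fragment files gave a start, an end and a strand for each fragment and kept duplicates. They held chromosomes 1 to 5 only and no fragment above 400 bp. How reads with several possible positions were placed is not given in the sources used here, so a value in repeated DNA depends on a choice that is unknown. In the deposited peak lists the authors gave each peak a fold enrichment, which is a ratio over a control or background that is not given in the sources used here. The authors also gave the −log10 of the p-value and of the q-value of each peak, and a summit. The deposited score was 10 times the −log10 p, without its decimals. The lowest −log10 p was close to 1.30 in every list, so that peaks that pass no correction for multiple tests were kept.

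The files held between 380830 and 23227603 fragments. Fragments with the same start, end and strand were counted once as a distinct fragment, which left between 265433 and 8712939 per file. Before any comparison, the files were set against each other for identical fragments in single-copy DNA, which is the set of 116184 bins of 1 kb whose density lay between 0.2 and 2 times the typical value. Replicates 1 and 3 of the same tRF shared most fragments of the smaller file, and so did replicates 2 and 4. The read names placed replicates 1 and 2 on another sequencing run than replicates 3 and 4. The 4 pairs were therefore taken to be 4 libraries that had each been sequenced on 2 runs, and the files of a pair were merged. The merged libraries are called preparation A (replicates 1 and 3) and preparation B (replicates 2 and 4) of each tRF. In the labels, only the replicate numbers tie the wild-type tRF library of a preparation to the mutant tRF library. The tests had been planned on 8 libraries, and n became 2 per group after the files had been examined. The fits of 8 files were kept as an alternative. Nothing in the labels says that the preparations came from separate plants, so p-values measure the spread between these preparations, which may be technical.

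Genes came from a table of the RefSeq annotation of assembly TAIR10.1 with 37899 nuclear genes, which gives no strand. The positions were tested against the files, because fragment density changes at gene ends. In 20 of 20 segments, 4 per chromosome, the contrast across gene ends was highest with the positions as given, between 1.13 and 1.36, against at most 1.05 with positions moved by 500 to 4000 bp. Promoters had been planned. Without strand they were replaced by gene flanks, the 1 kb on both sides of each gene, and all results on flanks were therefore chosen after the files had been examined. A fragment was counted where its midpoint lay. Libraries were scaled by the median ratio over bins of 10 kb. Regions with a mean of at least 10 fragments per library were tested with limma 3.58.1 in R 4.3.3 (voom with an offset of 0.5, empirical Bayes moderation, Benjamini-Hochberg adjustment), and a region was called at an adjusted p under 0.05. Folds are wild-type minus mutant tRF on the log2 scale. The counts were made here from fragments, so the count models built for deposited counts were not used. tRNA genes were summed over the 20 amino acids. Intervals of ratios of fragments are exact Clopper-Pearson 95% intervals. They cover counting error only, since fragments amplified by PCR are not independent molecules. They were also computed on the same counts that picked the regions, so an interval that excludes 1 is no evidence of a difference.

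The limma step was tested on simulated data with 200 regions changed 4-fold and a coefficient of variation of 20% between libraries. It recovered 86% of the changed gene bodies among 32538 regions, 65% of the changed flanks among 37898 and 15% of the changed 1 kb bins among 117719, and 6.01%, 2.26% and 0% of the calls were wrong. The simulated libraries held no difference between preparations, and regions with the lowest and highest counts were not changed. Recovery in the real data can therefore be lower. The overlap step was tested with 3000 simulated peaks: with 0, 100 and 600 shared peaks planted it estimated an excess of -6.36, 94.9 and 578 peaks.

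High-copy arrays were found from the data as joined 1 kb bins of at least 10 times the typical density, at most 5 kb apart, with a summed density of at least 100. This left 18 arrays out of 41 regions. An array was put in the satellite group when fragment starts recurred at a multiple of the repeat unit of the centromeric satellite within 3 bp, in the 500 bp repeat group by the same tolerance, and in the rRNA group when it held an annotated rRNA gene. The dense block is the longest run of 10 kb bins at 2 or more times the typical density. The array groups and the dense block were defined after the files had been examined. Densities are relative to single-copy DNA of the same library. The share of distinct fragments in 9 classes of the genome was compared by an exact two-sided permutation test over the 6 arrangements of 4 libraries, whose smallest p is 0.333. Differences within preparations were compared by an exact sign-flip test, whose smallest p is 0.5. No threshold of 0.05 can be reached with either.

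Peaks were compared as called by the authors for each replicate. A peak was shared when it overlapped a peak of the other list by 1 bp or more, against 1000 random placements on the same chromosome. The smallest two-sided permutation p is 0.002. The lists of a preparation were joined before the preparations were compared. A peak belonged to a gene when its summit lay in the gene or within 1 kb of it. Gene lists were set against 10000 random lists of protein-coding genes of the same lengths. Peaks of 2 or more replicates had been planned for this, and peaks of both preparations were used after the pairs of files had been found. Reads in peaks were tested only in peaks of the other preparation, since a list made from a library cannot test that library, and the ratio in a preparation's own peaks is given without a test.

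There were 13 gene lists, fixed before the data were examined: pattern-triggered immunity (PTI) signalling, NLR resistance genes, salicylic acid and systemic immunity, jasmonate and ethylene, camalexin with glucosinolates and callose, RNA silencing with DNA methylation and RNases, photosynthesis, flower with seed and meristem regulators, housekeeping, abiotic stress, the WRKY family, CRK receptor kinases and ribosomal proteins. They were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. The rule for named genes was also fixed before the data were examined. Since no gene was called, it takes the 10 gene bodies and the 10 flanks with the smallest p, the 15 genes with a peak in the most replicates ranked by the lowest fold enrichment, and up to 4 members of each list by the same rank.

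The alternatives were other scalings (total reads, quantiles), all reads with duplicates, other filters on low counts, a replicate block, sample quality weights, limma-trend, thinning to the smallest library, other widths of bins and flanks, stricter peak lists and overlaps, and leaving out each replicate. Added after the data were examined were the fits of 8 files, leaving out a merged library, fragments kept in 1 library each, thinning before duplicates were removed, fragments of 140 to 180 bp, overlaps in single-copy DNA alone, and gene bodies alone for the peak lists. Settings on mapping quality were not run, since the files give none. Organelle DNA, transposons as a class and the base sequence of peaks were not analysed here. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.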

Results

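To find the chromatin regions that a nuclear tRNA-derived fragment (tRF) meets, biotin-tagged tRF of wild-type or mutant sequence was infiltrated into Arabidopsis leaves for 1 h, and the DNA found with it was sequenced. The series comes from work on tRFs in plants infected with Pseudomonas syringae. There were 4 samples with the wild-type tRF and 4 with the mutant tRF. With the wild-type tRF, replicates 1 to 4 held 2829113, 3351395, 21736470 and 23227603 fragments, of which 2154442, 2471392, 7319623 and 8712939 were distinct. With the mutant tRF they held 975913, 380830, 7670980 and 3128582 fragments, of which 667854, 265433, 2471822 and 1387608 were distinct. Replicates 3 and 4 were therefore read more deeply than replicates 1 and 2, and the wild-type tRF more deeply than the mutant tRF at each number.

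Replicates 1 and 3 of the same tRF held the same DNA molecules, and so did replicates 2 and 4. Of the single-copy fragments of the smaller file of such a pair, between 73.7% and 90.0% were found with identical ends in the larger one. The value was between 0.906% and 30.2% for files of different libraries, and at most 0.114% in any pair after the fragments of 1 file had been moved by 5 or 12 bp. The files were counted as 4 libraries, preparations A and B of each tRF, with n = 2 per group. The merged libraries held 7626718 (wild-type, A), 2578588 (mutant, A), 9194960 (wild-type, B) and 1459755 (mutant, B) distinct fragments.

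**Figure D1:**
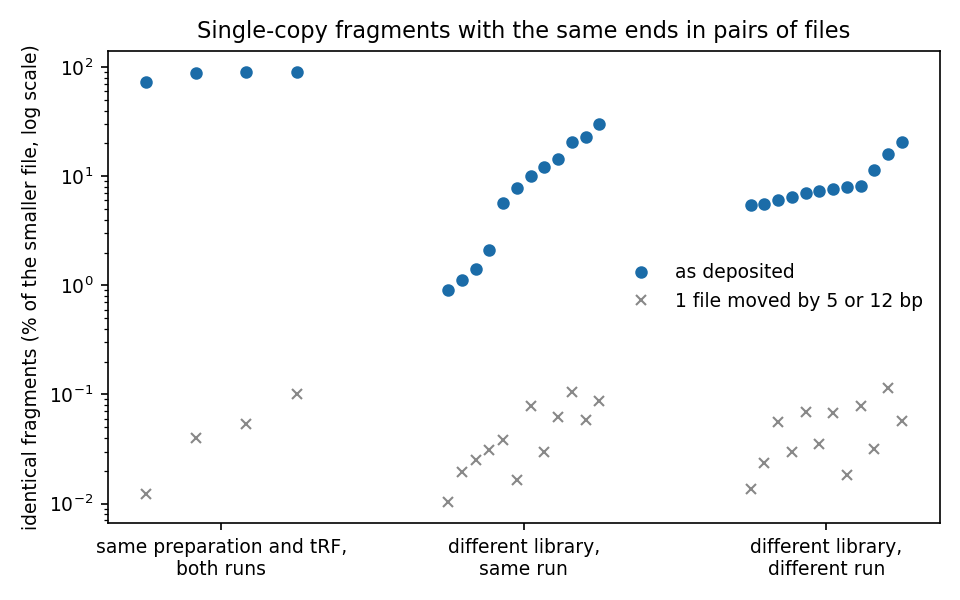
Share of single-copy fragments with identical ends in each of the 28 pairs of files (vertical axis in percent of the smaller file, log scale), by kind of pair, with circles for the files as deposited and crosses after 1 file was moved. The 4 pairs of the same preparation and tRF sit between 73.7% and 90.0%, and all other pairs between 0.906% and 30.2%.

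In percentage points, the largest difference among the 9 classes lay in the centromeric satellite, while as a ratio of shares that of the dense block described below was larger. Satellite arrays held a smaller share of distinct fragments with the wild-type tRF (16.0% ± 7.22, SD, n = 2) than with the mutant tRF (26.7% ± 7.47, SD, n = 2). The share was 10.9% against 21.4% in preparation A and 21.1% against 31.9% in preparation B. Relative to single-copy DNA of the same library, the 10 satellite arrays (149 kb in total) had a log2 wild-type over mutant density of -1.28 in A and -0.74 in B. The array on chromosome 3 at 13587001 to 13593000 was the densest of them, at 1050 times the single-copy density with the wild-type tRF and 2594 times with the mutant tRF in A, and at 2838 and 5528 times in B.

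Arrays of rRNA genes held a higher share of fragments with the wild-type tRF, at 10.5% against 9.47% in A and 18.7% against 10.1% in B (14.6% ± 5.85 and 9.81% ± 0.481, SD, n = 2). Relative to single-copy DNA their log2 ratio was -0.17 in A and 0.74 in B. The 2 arrays of a 500 bp repeat, on chromosomes 4 and 5, had log2 density ratios of -0.43 in A and 0.28 in B. A block of 270 kb on chromosome 2 (3240001 to 3510000), where the nuclear genome of Arabidopsis is known to carry a copy of mitochondrial DNA, was denser with the wild-type tRF, at 3.40 against 2.38 times the single-copy density in A and 5.92 against 2.57 times in B, and held 0.572% ± 0.0442 against 0.271% ± 0.0483 of the fragments (SD, n = 2). It contains 183 genes, 93 of them protein-coding. Protein-coding gene bodies held 33.6% ± 7.79 of the fragments with the wild-type tRF and 30.8% ± 4.95 with the mutant tRF, their 1 kb flanks 10.1% ± 4.96 and 7.84% ± 2.63, and other annotated genes 6.81% ± 0.304 and 5.49% ± 1.01 (SD, n = 2). Remaining DNA held 14.6% ± 1.62 and 15.9% ± 0.153. The 4 arrays in none of the groups (30 kb) were left in the gene, flank and remaining classes, which are therefore not free of high-copy DNA. Their log2 density ratios lay between -1.37 and 0.12 in A and between -0.93 and 0.69 in B. The densest of them, on chromosome 4, was at 840 (A) and 2347 (B) times the single-copy density with the wild-type tRF. With the mutant tRF it was at 2117 and 4456 times. Its log2 ratios were -1.33 (A) and -0.93 (B), and those of the array on chromosome 1 were -1.37 and -0.81, near those of satellite arrays. The arrays on chromosomes 2 (0.12 and 0.69) and 3 (-0.22 and 0.36) were not. How much of the difference in remaining DNA came from these arrays was not computed. tRNA genes held 0.0350% ± 0.00293 and 0.0281% ± 0.00416. Shares of a library are parts of a whole. Wild-type minus mutant tRF, the satellite share differed by -10.5 (A) and -10.8 (B) percentage points, which lowers the other shares of the mutant tRF. A higher share with the wild-type tRF in genes, flanks or tRNA genes therefore need not be a higher density outside the satellite.

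None of the 9 classes passed. The exact permutation test gave p = 0.333 for satellite arrays, rRNA arrays, the dense block, tRNA genes, other annotated genes and remaining DNA (adjusted p = 0.5), which is the smallest p that 2 libraries against 2 allow. For the satellite it rests on 21.1% (wild-type, B) against 21.4% (mutant, A): the exact p was 0.667 with all reads and without replicate 3 or 4, and also for its density relative to single-copy DNA, where that of rRNA arrays was 1. For the share of rRNA arrays it rests on 10.5% (wild-type, A) against 10.1% (mutant, B). Their exact p was 0.667 without replicate 3 and with fragments kept in 1 library each. It was also 0.667 for tRNA genes without replicate 3 and for other annotated genes with all reads. The fragment files hold no organelle chromosomes, so mitochondrial DNA cannot be told from its nuclear copy in the dense block. With fragments shared between libraries kept in 1 library each, the log2 ratio of the dense block was 0.25 in A and 0.48 in B (mean 0.36, against 0.86 before, with the larger drop in B), and that of the satellite moved to -1.55 and -1.48; this filter removed single-copy fragments alone, 43.2% of them in mutant preparation B and 3.40% in wild-type preparation A, and so lowered the reference density unequally.

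**Figure D2:**
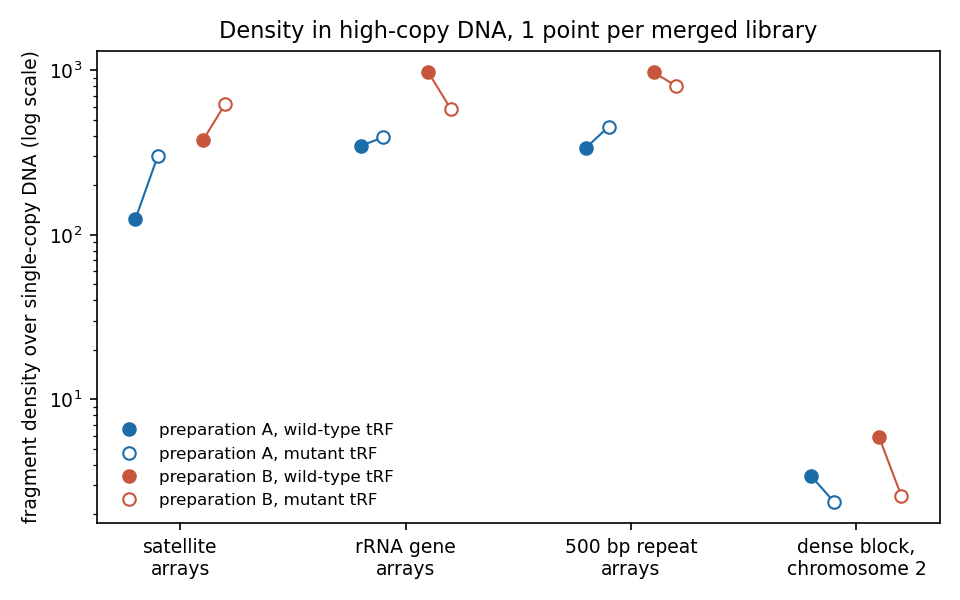
Fragment density in high-copy DNA relative to single-copy DNA of the same library (vertical axis, log scale), with 1 point per merged library, filled for the wild-type and open for the mutant tRF, and a line joining the libraries of a preparation. In satellite arrays the open points (303 and 629) lie above the filled ones (124 and 376) in both preparations, and in the dense block they lie below.

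Whether any gene was bound more with one tRF than with the other was asked of gene bodies, of gene flanks and of 1 kb bins. No gene body, flank or bin was called by limma-voom with all 4 libraries, median-ratio scaling and no block. That fit counts differences between preparations as spread within a tRF. With a replicate block, which pairs the libraries of a preparation, limma-voom called 0 gene bodies, 15 flanks (11 higher and 4 lower) and 1 bin (lower). All higher flanks but that of AT2G07707 had 0 fragments in mutant preparation B, the smallest library. The folds in preparations A and B were not correlated across regions. The correlation of the folds across regions, which are not independent replicates, was -0.03 over 33107 gene bodies, 0.01 over 37898 flanks and -0.01 over 118832 bins, and 49.7%, 50.0% and 49.5% of the regions had the same sign in both preparations. Counting noise alone pulls such a correlation towards 0. Mutant preparation B held 577694 single-copy fragments over 116184 bins of 1 kb. These values therefore cannot tell absent effects from effects that noise hides.

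The 10 gene bodies with the smallest p all missed the threshold (limma, adjusted p = 1.00 for each). Of these, 5 lay in the dense block of chromosome 2 and had more fragments with the wild-type tRF: AT2G07806 (log2 fold 1.11 ± 0.23, SE, n = 2 per group; 826 and 724 fragments against 107 and 50; 0.64 with fragments kept in 1 library each), AT2G07659 (1.46 ± 0.31; 0.65 without replicate 4), AT2G07739 (1.23 ± 0.30; 0.77 without mutant preparation A) and AT2G07775 (1.37 ± 0.36), together with the pseudogene AT2G07809. Outside the block, UPI (AT5G43580), a serine protease inhibitor, had 39 and 27 fragments with the wild-type tRF and 1 and 0 with the mutant tRF. That is a ratio of 14.4 with a 95% interval of 2.49 to 576. AT1G34910 had 25 and 28 against 1 and 0 (ratio 11.5, 1.98 to 464), and AT2G07809 had 34 and 33 against 1 and 0 (14.6, 2.53 to 584). These genes were picked by their small p from the same counts, so the intervals do not have their stated coverage. The fitted log2 folds of UPI, AT1G34910 and AT2G07809, which depend on the prior count, dropped from 2.93, 2.60 and 2.95 to 1.41, 1.08 and 1.44 without mutant tRF replicate 4. AT5G24050 (-1.27 ± 0.29; -2.13 with libraries thinned to the smallest), AT5G59470 (-1.19 ± 0.29; -0.78 without replicate 4) and AT2G19790 (72 and 58 fragments against 39 and 17) had fewer scaled fragments with the wild-type tRF, and AT2G19790 was at -1.61 without mutant tRF replicate 4.

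Among the 10 flanks with the smallest p, the flanks of AT2G07707 (2.24 ± 0.50, SE, n = 2 per group), AT2G07715 (1.77 ± 0.40) and AT2G07718 (1.45 ± 0.35), all in the dense block, were higher with the wild-type tRF. The other 7 were lower: TAA1, a tryptophan aminotransferase of auxin synthesis (-1.15 ± 0.26), AT4G31650 (-1.03 ± 0.24), the pseudogene AT5G49746 (-1.06 ± 0.24), HMGB2, which encodes a high mobility group protein (-1.04 ± 0.24), FOLB2 of folate synthesis (-0.96 ± 0.22), AT5G06400 (-1.08 ± 0.26) and the non-coding RNA gene AT1G48315 (-1.05 ± 0.25). Their adjusted p was 0.988 in limma without a block. With a replicate block, which rests on 2 pairs, limma called only AT2G07707 of these 10 (adjusted p = 0.00605). Without mutant tRF replicate 4 the log2 fold of TAA1 was 0.57 and that of AT2G07715 was 0.10 (0.26 without replicate 4), and with fragments kept in 1 library each that of AT5G06400 was 0.99. Of the other 7 flanks, all but that of AT2G07707 moved by over 1.5 times under some setting: HMGB2 was at -1.59 without mutant tRF replicate 4 and at -0.47 with reads thinned before duplicates were removed, AT4G31650 was at -1.69 without replicate 4 and at -0.65 without mutant tRF replicate 3, FOLB2 was at -2.03 without mutant tRF replicate 4, AT5G49746 at -0.37 with libraries thinned to the smallest, AT1G48315 at -0.42 without mutant preparation A and AT2G07718 at 0.72 without wild-type tRF replicate 3.

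At an unadjusted p under 0.05, limma-voom had 138 gene bodies higher and 357 lower of 33107 tested. It had 447 flanks higher and 1052 lower of 37898, and 970 bins higher and 3883 lower of 118832. Each total lay below the share of 0.05 that no difference would give. None is therefore an excess of weak signals in this fit, which has no block. With a replicate block there were 334 gene bodies higher and 1305 lower. There were then 994 flanks higher and 1199 lower, and 1652 bins higher and 8014 lower. The totals of flanks and bins with the block lay above that share. The low totals without a block therefore cannot show that weak signals are absent. The smallest adjusted p in limma-voom without a block was 1.00, 0.988 and 0.960. Quantile normalization called 4 gene bodies. Limma-trend called 0 gene bodies, 1 flank (AT2G07707) and 0 bins. With 2 libraries per group the counts hung on single libraries. Leaving out wild-type preparation A gave 604 gene bodies and 2206 flanks, leaving out wild-type preparation B gave 3571 flanks, leaving out mutant preparation A gave 355 flanks and 1736 bins, and leaving out mutant tRF replicate 4 gave 26 bins.

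**Figure D3:**
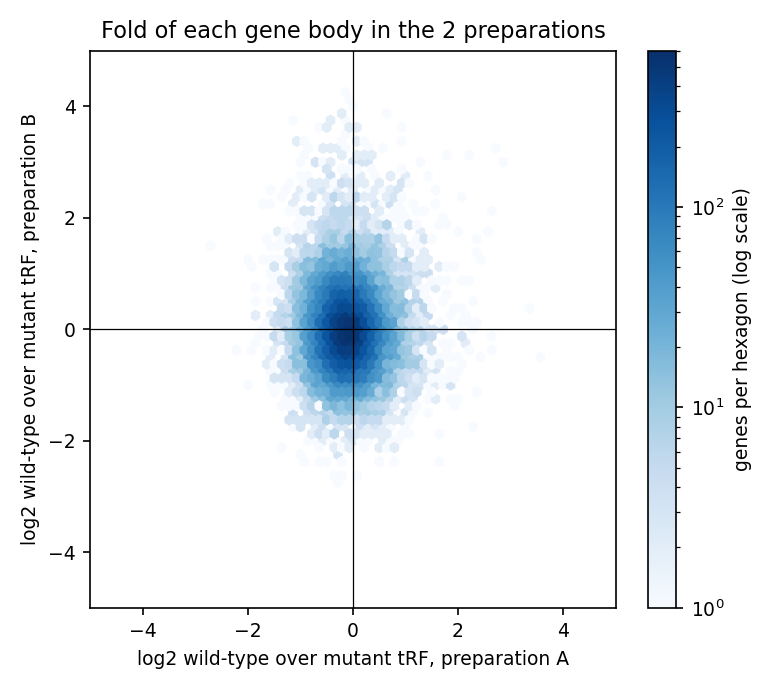
Log2 fold of wild-type over mutant tRF for 33107 gene bodies in preparation A (horizontal axis) and preparation B (vertical axis), shaded by the number of genes per hexagon on a log scale. The cloud has no slope (correlation -0.03), which counting noise in the small mutant tRF libraries can also give.

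No gene list fixed beforehand was called by camera in gene bodies or flanks. The jasmonate and ethylene genes came closest, in their flanks: 18 of 25 members were higher and 7 lower with the wild-type tRF, with a median log2 fold of 0.15 (limma camera, adjusted p = 0.995), a median of 0.16 in preparation A and -0.01 in B. Photosynthesis genes, which are active in leaves, had a gene body median of 0.04 (14 of 25 higher), and the flower, seed and meristem regulators, which are silent there, one of 0.03 (10 of 20 higher). For immune genes the gene body medians were -0.02 for PTI signalling (10 of 20 higher), -0.01 for NLR resistance genes (11 of 23), -0.06 for salicylic acid and systemic immunity (8 of 20), -0.05 for camalexin, glucosinolates and callose (9 of 19), 0.01 for the WRKY family (34 of 67), -0.01 for CRK receptor kinases (20 of 40) and -0.02 for jasmonate and ethylene (11 of 25). They were -0.03 for RNA silencing, DNA methylation and RNases (15 of 31), -0.10 for abiotic stress (3 of 12), -0.04 for ribosomal proteins (32 of 67) and 0.00 for housekeeping genes (6 of 11).

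Scaling by total reads moved the median of all gene bodies from -0.05 to 0.12, more than most of these medians differ from 0, so their signs depend on the scaling. In the flanks the other medians lay between -0.10 (NLR resistance genes) and 0.07 (camalexin, glucosinolates and callose). In no list was a member called, over all genes tested or adjusted over the list alone, and at an unadjusted p under 0.05 a list had at most 3 members (RNA silencing, DNA methylation and RNases, flanks). Over the 26 tests the smallest adjusted p was 0.995 with the preset correlation, 0.998 with an estimated correlation and 0.953 with fry. With fragments kept in 1 library each, a setting chosen after the data had been examined, fry called the flanks of ribosomal proteins (adjusted p = 0.0396; median 0.01, 35 of 67 higher) and camera called none. Camera compares a list with all other genes, whose median was -0.05 in gene bodies, and its direction was upward for the CRK, NLR, PTI, RNA silencing and salicylic acid lists although their gene body medians were below 0. In flanks the median and the mean had opposite signs for the CRK, photosynthesis, PTI and RNA silencing lists.

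The tRNA genes themselves showed no difference that passed. Summed by amino acid, leucine tRNA genes had the smallest p (log2 fold 0.47 ± 0.26, SE, n = 2 per group; 230 and 219 fragments against 54 and 17), followed by asparagine (-0.45 ± 0.30), methionine (0.44 ± 0.32) and cysteine (0.56 ± 0.42). The values of the other 16 families lay between -0.34 (glutamine) and 0.47 (isoleucine). By limma 0 of 20 families were called, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.739. The values hung on single files: without mutant tRF replicate 4 leucine was at 0.07 and methionine at -0.30 (0.23 without the dense block, which holds 3 of its 24 genes), and cysteine was at 2.02 without mutant tRF replicate 3 and at 1.18 with all reads. They also hung on the width counted. With 200 bp on each side of the genes, leucine was at 0.24, asparagine at -0.08, methionine at 0.21 and cysteine at 0.17.

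The authors' peak lists of the wild-type tRF held 23668, 17403, 1677 and 8988 peaks for replicates 1 to 4. The median peak was 191, 231, 207 and 254 bp wide, with a median fold enrichment by the authors of 2.43, 2.52, 2.26 and 2.32. Few peaks passed a correction for multiple tests: 3.07%, 19.1%, 0.0596% and 27.6% of the peaks had a q-value under 0.05. At a q-value under 0.01 there were 100, 1613, 1 and 1389 peaks, and at a fold enrichment of 3 or more there were 3349, 4102, 113 and 1419. The replicates with the deeper files, 3 and 4, had the shorter lists.

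Peaks recurred between the sequencing runs of a library and, once the lists of a preparation were joined, little above chance between preparations. Of the peaks of replicate 3, 63.6% overlapped a peak of replicate 1, against 8.80% by chance, and of those of replicate 4, 66.0% overlapped one of replicate 2, against 8.61%. Of the 24271 joined peaks of preparation A, 9.42% overlapped a peak of preparation B, against 8.82% over random placements (1.07 times chance, permutation p = 0.004). In the reverse direction it was 10.9% against 10.4% (1.04 times, permutation p = 0.0400). Single lists varied more: peaks of replicate 3 were found in replicate 4 at 2.89 times chance, those of 4 in 3 at 2.47 times and those of 3 in 2 at 1.66 times, but those of 1 in 4 at 0.892 times. Protein-coding genes with a summit in the gene or within 1 kb of it numbered 8400 in both preparations, where independent lists would give 8140, and 254 had one in all 4 lists. The expected number treats all genes alike, although longer genes hold more peaks by chance, so the excess does not show shared genes. No expected number was computed for the 254.

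The strongest peaks were shared above chance, and most of the shared ones lay in the dense block of chromosome 2. With the 1677 peaks of the smallest p of each list, 137 of 3127 regions of preparation A were found in B (4.38% against 1.48% by chance, 2.96 times), and 83 of the 137 (60.6%) lay in the block. In single-copy DNA outside it the overlap of these strongest peaks was 26 of 2920 (1.01 times chance, permutation p = 1). The overlap over all peaks was below chance without replicate 2 (0.967 times) and 1.84 times chance without replicate 1.

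**Figure D4:**
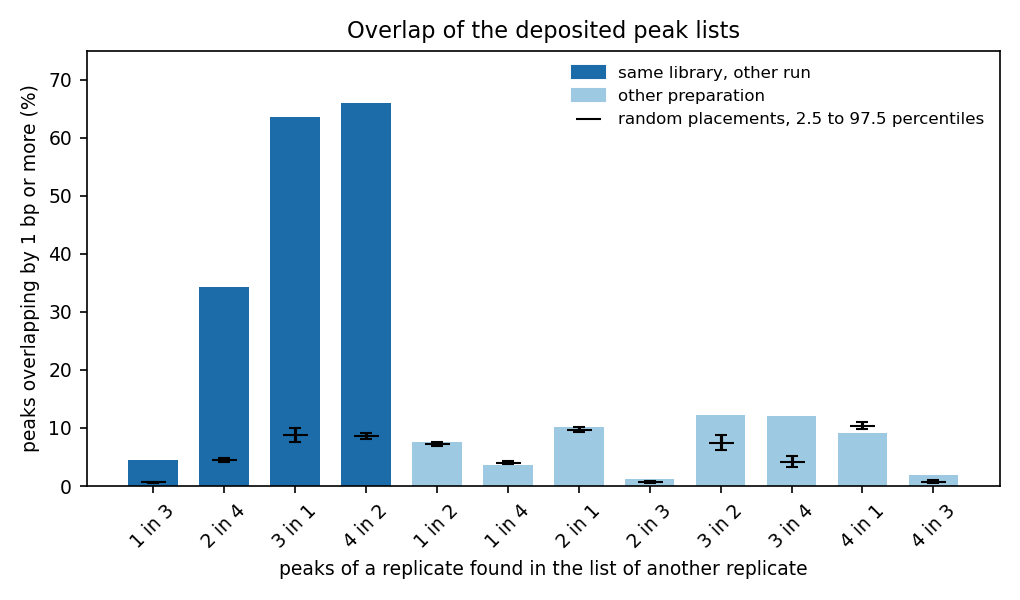
Percentage of the peaks of each replicate that overlap a peak of another replicate (bars; dark for the other run of the same library, light for the other preparation), with the mean and the central 95% of 1000 random placements (black marks). Peaks of replicates 3 and 4 found in replicates 1 and 2 reach 63.6% and 66.0%, and no bar between preparations exceeds 12.3%.

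Among the 15 genes with a peak in all 4 lists and the highest lowest fold, 8 lay in the dense block. AT2G07806 ranked first, with fold enrichments by the authors of 3.23, 3.84, 3.38 and 3.25 in replicates 1 to 4. The others there were AT2G07735, AT2G07706, AT2G07707, AT2G07717, AT2G07661, AT2G07725 and AT2G07726, with a lowest fold between 2.84 and 3.07. Some peaks counted for neighbouring genes. AT2G07706 and AT2G07707 had the same summits in replicates 1 and 3, and AT2G07725 and AT2G07726 in replicates 1 to 3. The 8 genes are therefore not 8 separate sites. The largest distance between the summits of a gene was between 310 bp (AT2G07726) and 5063 bp (AT2G07717) in the block and between 772 bp (AT2G45600) and 12470 bp (AT5G27970) outside it, so that a gene in all 4 lists need not hold a shared site. At AT5G27970 on chromosome 5 the summits of replicates 1 and 3 were at 10003822 and 10003828, and those of replicates 2 and 4 at 10016267 and 10016292, in the flanks at opposite ends of the gene. At AT4G32780 on chromosome 4 they were at 15808119 and 15808140 in a flank, and at 15810673 and 15810676 in the gene. At AT2G45600 on chromosome 2 they were at 18790936 and 18790950, and at 18790178 and 18790182, all in the gene. BRM, the ATPase of a chromatin remodelling complex, had its 4 summits within the gene, spread over 4648 bp, with a lowest fold of 3.02. AT1G29090 and the pseudogenes AT4G03790 and AT4G03880 had lowest folds of 2.92, 2.81 and 2.81, with summits up to 1832, 1863 and 1559 bp apart.

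With summits in the gene or within 1 kb of it, no immune or silencing list differed from genes of matched length by a test that passed, in the number of members with peaks in both preparations. Summits in the gene body alone, where the WRKY family did pass, are given below. For RNA silencing, DNA methylation and RNases it was 19 of 31 genes against 15.8 by chance, with SGS3, RDR1, CMT3 and AGO1, which act in small RNA pathways and DNA methylation, each in 3 lists at a lowest fold by the authors of 2.77, 2.69, 2.65 and 2.57. For the WRKY family of transcription factors it was 27 of 67 against 19.6, with WRKY6 (1.83) and WRKY18 (1.77) in 4 lists and WRKY61 (3.12) and WRKY69 (2.77) in 3. For CRK receptor kinases it was 18 of 40 against 15.3, with CRK29 and CRK10 (2.32 each) and CRK39 (1.94) in 3 lists. PTI signalling had 8 of 20 against 8.07, with RBOHD, the oxidase of the immune burst (2.61), MKK5 (2.32), CPK28 (2.17) and MPK4 in 3 lists. NLR resistance genes had 6 of 23 against 11.3, below the range of random lists (7 to 16; permutation p = 0.0378, adjusted p = 0.451), with ZAR1 (2.43) and RPP4 (2.35) in 3 lists. Any 3 lists include both runs of 1 library, so 3 lists stand for 2 preparations. In all, 3353 genes had a peak in 3 or more lists, and replicate 1 alone had one at 16063 of 27444 protein-coding genes. The summits behind these counts need not lie at 1 site: those of AGO1 were up to 5969 bp apart, of RPP4 5493, of RBOHD 3982, of MKK5 3818, of CMT3 2725 and of SGS3 2505 bp, and those of WRKY61 157 bp. The salicylic acid list had 7 of 20 against 7.08, with NPR1 (2.65) and PAD4 (2.08) in 3 lists, and jasmonate and ethylene had 11 of 25 against 8.41, with VSP1 (2.65), OPR3 (2.43), CTR1 (2.31) and JAZ1 in 3.

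None of the remaining lists passed either. Camalexin, glucosinolates and callose had 4 of 19 against 6.11, with the callose synthase gene GSL05 (lowest fold 2.06) in 3 lists. Abiotic stress had 4 of 12 against 3.64, with LTI78 (2.83), ERD10 (2.26) and the chaperone gene HSP101 (2.09) in 3. Photosynthesis had 9 of 25 against 6.17, with LHCB2.2 (2.14), LHCA2 (2.08) and RBCS1B (2.07) in 3, and the flower, seed and meristem regulators 6 of 20 against 6.85, with KNAT1 (2.43) and LEC2 (1.79) in 3. Ribosomal proteins had 14 of 67 against 16.0, with RPS28 (2.16) and PSRP6 (2.11) in 3, and housekeeping genes 4 of 11 against 3.78, with PEX4 (1.77) and ACT7 (1.75) in 3. Of the 13 lists, 0 passed by the permutation test over random lists of matched length, and only the NLR list had an unadjusted p under 0.05. Counting summits in the gene body alone gave 2 lists, the WRKY family (21 of 67 against 9.14, adjusted p = 0.0026) and photosynthesis (8 of 25 against 2.23, adjusted p = 0.0143), a setting chosen after the data had been examined.

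Where peaks fell also differed between preparations. In replicates 1 and 3, 21.2% and 30.8% of the summits lay in the flanks of protein-coding genes, against 19.0% by chance, and 7.67% and 6.56% in other annotated genes, against 9.95% and 10.1%. In replicates 2 and 4 it was the reverse: 6.32% and 4.37% lay in flanks, against 19.0%, and 20.5% and 28.1% in other annotated genes, against 10.1%. In protein-coding gene bodies the summits were at 1.00, 1.13, 0.656 and 0.994 times chance in replicates 1 to 4, so that the excess over all 51736 peaks (55.8% against 54.0%, 1.03 times, permutation p = 0.002, the smallest possible) came from replicate 2 under uniform placement; the pooled test also counts sites found in both runs of a library as separate peaks. Counting whole peaks ended that excess (0.998 times), and a background weighted by mutant tRF fragments turned the deficit of preparation A (0.980 times) into an excess (1.28 times) and raised the excess of preparation B from 1.08 to 1.56 times. That background includes the high-copy arrays. Satellite arrays alone held 21.4% (A) and 31.9% (B) of the mutant tRF fragments. Gene bodies held only 41.5% and 37.5% of this background, so their ratio rises for any peaks outside arrays. tRNA genes held 0.0580% of all summits against 0.0395% (1.47 times, permutation p = 0.0559). They held more than chance among peaks found in both preparations (3.97 times, permutation p = 0.004) and in replicate 2 (2.77 times, permutation p = 0.002), while replicate 1 was at 0.620 times and replicate 3 had 0 summits there. The numbers were small, with 19 summits for replicate 2. For the peaks found in both preparations there were 8 summits in 7 tRNA genes, 5 of them from replicate 2 and 2 in the dense block. Most of these genes therefore held a summit of a single list, and the overlapping peak of the other preparation had its summit outside the gene.

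Fragments in the peaks of the other preparation tested whether peak regions drew more DNA with the wild-type tRF. Over the 18660 single-copy peaks of preparation B, the ratio of wild-type to mutant tRF density in preparation A was 0.961. That ratio was below the range of random placements (0.991 to 1.01). In preparation B it was 1.03 over the 23948 peaks of A, above that range (0.987 to 1.01). The mean log2 ratio was -0.00 (exact sign-flip test, p = 1, n = 2 preparations, smallest p 0.5). Density in these peaks was above that of single-copy DNA with either tRF, at 1.11 (wild-type) and 1.15 (mutant) in A and at 1.14 and 1.11 in B. Identical fragments in different libraries limit this test. Of fragments with 1 read, 21.0% of mutant and 7.68% of wild-type tRF replicate 3 were found in wild-type tRF replicate 4. With 8 or more reads it was 9.79% and 9.16%. Such sharing can raise mutant tRF density in these peaks, so a ratio under 1 cannot show that they drew no more wild-type tRF DNA. In the peaks of its own preparation, which were called on the same fragments, the ratio was 1.63 in A and 1.73 in B.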

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

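The 2 tests on identical fragments were chosen after the result was seen; the other tests were written down before their own values, but for patterns already seen in the data. A search for samples far from their group covered 8 measures in 16 groups of 4 files, and 0 files lay past Dixon's critical value. Since 2 files of a library lie close together and mask each other in this test, it says nothing on whether a whole library stood apart.

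Identical fragments in different libraries drew attention because they lie outside the measures compared between the tRFs and were far above the level after moving. The highest share was 30.2%, between wild-type tRF replicate 3 and mutant tRF replicate 4, which are of different tRFs and different preparations. Chance matches of independent molecules with evenly placed ends are argued against, since the share was at least 56.9 times that found after moving the fragments of 1 file. Moving also undoes any preference of fragment ends for certain positions. The test therefore cannot decide on independent molecules with recurrent ends. Reads assigned to the wrong library could produce such sharing, and stay open: fragments with 8 or more reads were found in another library 2.21 times as often as fragments with 2 reads (median over 12 ordered pairs), but moved fragments showed a ratio of 1.70, a control required only after both values had been seen, and an earlier test was dropped because its selection fixed its outcome. At the other end, fragments with 1 read in mutant tRF replicate 4 were found in wild-type tRF replicate 3 more often than those with 3 to 4 reads (36.1% against 7.45%; moved, 0.0391% against 0.0539%), as were those of mutant tRF replicate 3 (29.7% against 9.46%), while the reverse search of wild-type tRF replicate 3 in mutant tRF replicate 4 gave 2.13% against 3.34%. These values, noticed in the data with no rule written beforehand, go with reads passing from the deeper to the smaller libraries, which would understate differences between the tRFs.

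Satellite arrays held a smaller share of the fragments with the wild-type tRF in both preparations. Unequal depth is argued against: thinning every library to the reads of the smallest kept at least 1.06 times the log2 difference. Fragment length is argued against as the whole cause, since fragments of 140 to 180 bp kept at least 0.725 of it. The placement of reads with several possible positions and a difference in how the libraries of the 2 tRFs were prepared stay open, and so does an effect of the tRF sequence, which is the group compared. This pattern was named, and rRNA arrays were left out of it, after the values had been seen.

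Relative to single-copy DNA, arrays of rRNA genes and of the 500 bp repeat had opposite directions in the preparations: log2 -0.17 in A and 0.74 in B for rRNA genes, and -0.43 and 0.28 for the 500 bp repeat. The share of all fragments in rRNA arrays was higher with the wild-type tRF in both (10.5% against 9.47% in A, 18.7% against 10.1% in B). The ratio of wild-type to mutant tRF density in the peaks of the other preparation also lay on opposite sides of 1, at 0.961 in A and 1.03 in B. These differences between preparations were not tested.

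Peaks recurred between the runs of a library and little above chance between the joined lists of the preparations. Rereading the same molecules is argued against as the whole cause, because wild-type tRF fragments new in the second run had 1.41 (A) and 1.79 (B) times the single-copy density in the peaks of the first run, and 1.28 and 1.77 times without those within 3 bp of an earlier fragment. New mutant tRF fragments were at 1.14 and 1.43 there, so part of this density is not particular to the wild-type tRF. Amplification or capture particular to a library was not tested separately. A shared set of sites hidden by low depth could not be settled: the lower ratio in the other preparation's peaks was 0.961, below random placements, while the other was above them, so neither bound set for this test was met. No biological explanation was tested for this pattern.

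The 4 libraries make 3 splits into 2 and 2, too few for a share under 0.05. Without a block, the real split called 0 gene bodies, 0 flanks and 0 bins by limma-voom. At an unadjusted p under 0.05 it had 138 and 357 gene bodies, 447 and 1052 flanks, and 970 and 3883 bins higher and lower. Each of these totals was below the share that no difference would give. For the real split, limma-trend called 0, 1 and 0. The highest other split, preparation A against preparation B, called 1625 gene bodies, 2963 flanks and 5099 bins, which points to a structure of the samples that follows the preparations. The remaining split called 0 in each.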

How the results depend on the processing

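Fits of 8 files, settings that leave out a merged library, fragments kept in 1 library each, thinning before duplicates were removed, overlaps in single-copy DNA, gene bodies alone for the peak lists, and all settings for flanks were chosen after the data had been examined.

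Some settings called gene bodies, flanks or bins, from 1 to 3571 of them. Quantile normalization gave 4 gene bodies. A replicate block, which pairs the libraries of a preparation, gave 0 gene bodies, 15 flanks (11 higher and 4 lower) and 1 bin, with AT2G07707 among the flanks, and with 8 files 1 gene body, 0 flanks and 274 bins. All higher flanks but that of AT2G07707 had 0 fragments in mutant preparation B, the smallest library. The flanks of SPS1, for example, had 98 and 62 fragments with the wild-type tRF and 18 and 0 with the mutant tRF. Limma-trend gave 1 flank. The pairing rests on 2 pairs, and the correlation it removes was 0.13 in gene bodies, 0.19 in flanks and 0.16 in bins. Leaving out a replicate or a merged library gave between 0 and 604 gene bodies, between 0 and 3571 flanks and between 0 and 1736 bins; a lone library was then assumed to vary like the other group. The calls came from leaving out wild-type preparation A (604 gene bodies, 2206 flanks), wild-type preparation B (3571 flanks), mutant preparation A (355 flanks, 1736 bins), mutant replicate 4 (26 bins) and replicate 4 (11 bins). In the flanks of TAA1 the log2 fold (-1.15) ranged from -1.42 without wild-type preparation A to 0.57 without mutant replicate 4, and was 0.04 without replicate 4. In those of AT5G06400 it was 0.99 with fragments kept in 1 library each, against -1.08.

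With fragments kept in 1 library each, the mean log2 density ratio was -1.52 for satellite arrays (-1.01 before) and 0.36 for the dense block (0.86 before); this filter removes single-copy fragments alone and unequally. The overlap of peaks between preparations (1.07 times chance) ranged from 0.967 without replicate 2 to 1.84 without replicate 1, and was 1.04 without replicate 3. It was 1.41 with a reciprocal overlap of 50%, 4.85 at a q-value under 0.01, 2.96 for equal numbers of the strongest peaks and 1.01 (permutation p = 1) for these in single-copy DNA. The total of peaks per replicate was 3103 at a q-value under 0.01 and 8983 at a fold of 3 or more, against 51736. The share of summits in gene bodies relative to chance moved from 0.980 to 1.28 in preparation A with a background weighted by mutant tRF fragments, which includes the high-copy arrays. It moved from 1.03 to 0.998 over all lists with whole peaks. In the other preparation's peaks the mean log2 ratio was 0.12 with all reads, and between -0.015 and 0.10 without a replicate, with 0.07 without replicate 3. Gene bodies alone gave 2 gene lists among peak genes. Fry with fragments kept in 1 library each called the flanks of ribosomal proteins.

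Scaling by total reads moved the median log2 fold of flanks from -0.00 to 0.12 and of bins from -0.02 to 0.08. Of the values under other settings, 848 for single items (regions, classes and peak lists) and 148 for summaries changed neither call nor direction or stayed within their spread, which does not mean that folds stood still: in the flanks of AT2G07715 the fold was 0.10 without mutant replicate 4, against 1.77. For single items 41 newly passed the threshold, 10 moved and 3 reversed, and for summaries 21 moved, 3 reversed and 2 no longer passed. Settings on mapping quality and on the base sequence of peaks were not run.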

Other observations

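All values here were chosen for description after the data had been examined. Mean fragment length differed between preparations more than between tRFs. It was 160, 189, 160 and 187 bp in replicates 1 to 4 with the wild-type tRF, and 160, 186, 159 and 181 bp with the mutant tRF. Most satellite arrays had fragment starts that recurred every 356 bp.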
